A study of Drosophila melanogaster with 3 samples.

How the data were processed

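ChIP-seq of GFP-tagged CoRest was measured in 3 biological replicates of transgenic Drosophila melanogaster embryos, numbered as in the labels; chromatin was sonicated to fragments of 200 to 800 bp, per the labels' protocols. All 3 belong to 1 group. Only peak lists were used here: 1 list per replicate, 1 pooled list and 1 list thresholded on reproducibility (IDR). Per the deposited file listings, the pooled list came from the 3 replicates' alignments, each list used the same 1 control file, and the thresholded list was derived from the replicate and pooled lists on the dm6 assembly. The peak caller, the IDR threshold, the aligner and the read numbers are not given in the sources used here. No mock precipitation, input or chromatin accessibility data were analysed here.

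The deposited peak signal is the authors' value, whose definition is not given in the sources used here. Its scale differed between lists (highest value 14527 in the pooled and 1989 in replicate 2), so signal was used only to rank peaks within a list. The deposited −log10 q-value of each peak was not used in any test, since 97.3% of the thresholded peaks shared the highest value. Each list's summits were taken as deposited, including 3 of the thresholded list that lay outside their interval. Coordinates are 1-based on dm6 and ranks are those of the pooled list unless a replicate is named. To compare lists of 1 length, the 8721 strongest peaks of each replicate were used, 8721 being the length of the thresholded list.

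Genes came from Ensembl release 115 and sequence from the RefSeq assembly of the same Release 6 genome, on chromosome arms 2L, 2R, 3L, 3R, 4 and X; chromosome lengths and the last peak on each chromosome were compared before use. There were 13945 protein-coding genes with 19607 start sites, and 23998 start sites of all genes; records of transposable elements were left out. A promoter peak had its summit within 500 bp of a protein-coding start site, and its gene was called bound. Other summits were placed in the order 5′ untranslated region, coding sequence, 3′ untranslated region, the rest of a gene (called intron, exons of non-coding genes included) and intergenic. Distal summits lay over 2 kb from any start site. A divergent promoter had start sites of opposite strand head to head within 500 bp; its plus-strand gene was counted.

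The promoter share was tested 1-sided against 1000 random placements on the same chromosomes. A thresholded peak was found in a replicate when summits lay within 100 bp, and clusters joined summit windows of 100 bp on each side, with chance from 100 placements. The 21 gene lists, of 766 genes with 1 in more than 1 list, were each tested against all other protein-coding genes with Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. A second value was the percentile among 10000 random lists matched on start sites and gene length, with 0.0002 as the smallest p. Of the listed symbols, 4 were matched through synonyms (nos as nanos, h as hry, Dl as Delta, phm as phtm). The 28 motif consensus sequences were searched on both strands within 100 bp of summits. Promoter controls were drawn with replacement from start sites over 1000 bp from any thresholded summit at the same offset, and distal controls were GC-matched to 2.5 percentage points. Motif shares were compared by Fisher's exact test, 2-sided, adjusted over the motifs, and ratios of motif shares were computed with 0.5 added to each count. Ratios of bound shares had 95% intervals on the log scale and Fisher's exact test. Tests over peaks and genes treat these as independent; the spread over replicates is given as mean ± SD.

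The gene lists, the motif sequences, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule named the 20 strongest promoter peaks found in all 3 replicates, the 6 strongest distal peaks, up to 4 bound and 2 unbound members of each list past the threshold, up to 2 bound members of other lists, and CoRest, Su(var)3-3, HDAC1, ttk, chn and l(3)mbt. The alternatives were other promoter and motif windows, other overlap rules, the 4360 strongest thresholded peaks, the 17442 strongest pooled peaks, flanking control windows, matched random lists, and each replicate left out in turn (for the thresholded list, keeping peaks found in both other replicates). After the data were seen, GC-matched placements, promoters and gene lists, ratios within 10 classes of promoter GC, promoters at least 80% unique, and 20 other control draws were added, as were genes with 1 start site and shares of genes with any distal summit. Promoter GC was the lowest, over a gene's start sites, of the 300 bases upstream. Uniqueness was the share of 31-base sequences within 500 bp of a start site that occur once in the assembly.

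The gene list, motif and promoter tests were also run on simulated data. With 13945 genes, lists of 40 genes drawn at 70% bound were called above other genes in 95% of 100 runs, lists at 5% were called below in 100%, and lists at the background of 35% were called in 0.579%. An M1BP site planted in 5% of 2600 windows was called in 100% of 20 runs, and other motifs in 0.741%. Both sets of windows were drawn at random in the same way, so these rates do not cover controls that differ in GC content or rarer motifs. With 40% of 8721 summits placed at promoters, a promoter share of 47.0% was set and 46.8% recovered. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.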

Results

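The data were chromatin immunoprecipitation sequencing (ChIP-seq) peaks of CoRest, the scaffold protein of a corepressor complex that holds the histone demethylase Su(var)3-3 and the histone deacetylase HDAC1. The protein carried a green fluorescent protein (GFP) tag in transgenic Drosophila melanogaster and was precipitated with an antibody against GFP from whole embryos of both sexes aged 0 to 24 hours. The samples formed 1 group of 3 biological replicates with no second condition, so the question addressed here is where in the genome the tagged protein was found. Each replicate list and the pooled list held 30000 peaks, and the authors' list thresholded on reproducibility held 8721 peaks with a median width of 444 bp. Peaks were compared with random placements, with other genes and with control windows, and shares are given for the thresholded list and, for most comparisons, as the mean over the 8721 strongest peaks of each replicate. No read counts were analysed here, so the sequencing depth is unknown, and intervals on shares cover counting error only.

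CoRest peaks lay mainly at promoters and in introns and were almost missing from coding sequence. Of the 8721 thresholded summits, 4144 (47.5%) lay within 500 bp of a protein-coding transcription start site, with 48.2% ± 2.33 (SD, n = 3) in the replicates. Random placements on the same chromosomes gave a mean of 11.4% and at most 13%, so the promoter share was 4.15-fold that of chance (1-sided p = 0.001 by permutation of positions, the smallest that 1000 placements can give). Introns outside promoters held 2873 summits (32.9%; replicates 32.8% ± 2.25, SD, n = 3), against 39.4% of random positions. Intergenic sequence held 1584 (18.2%; replicates 17.6% ± 1.05, SD, n = 3), against 30%. Coding sequence outside promoters held 13 summits (0.149%; replicates 0.157% ± 0.0350, SD, n = 3), against 13.9% of random positions and 4.44% of random positions with the same GC content (lowest 3.99%). Untranslated regions outside promoters held 37 summits at the 5′ side (0.424%, against 0.788% by chance) and 70 at the 3′ side (0.803%, against 4.52%).

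**Figure D1:**
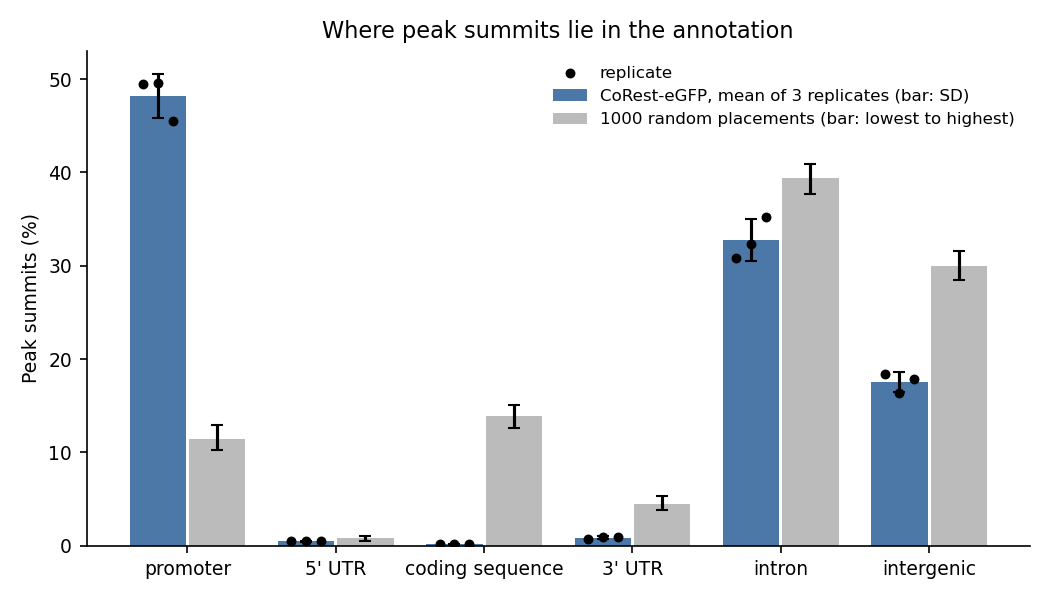
Share of peak summits (%) in each annotated feature for CoRest-eGFP (blue, mean of 3 replicates with SD, points for replicates) and for 1000 random placements (grey, mean with lowest and highest). Promoters held 48.2% of summits against 11.4% by chance, and coding sequence 0.157% against 13.9%, or 4.44% at positions of the same GC content (not drawn).

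At promoters the summits sat just upstream of the start site. The median position was -114 bp (replicates -110 bp ± 11.5, SD, n = 3), 86.1% of promoter summits were upstream (replicates 84.5% ± 1.84, SD, n = 3), and 72.1% lay within 200 bp of the start site. The fullest 50-bp interval ran from -150 to -100 bp and held 762 of the 4144 promoter summits. Summits were AT-rich: the GC content within 100 bp of the thresholded summits was 34.4% (replicates 34.7% ± 0.672, SD, n = 3), against 42.2% at random positions and 42.7% ± 0.122 (SD, n = 3) at 1 kb from the replicates' summits. It was 31.2% in the strongest 10% of thresholded peaks and 36.2% in the weakest 10%. Genes with AT-rich promoters were bound most often: of genes with a promoter GC of 10.7 to 28% a share of 45.9% ± 2.27 was bound, and of those with 48.3 to 68% a share of 15.4% ± 1.90 (both SD, n = 3). Promoter GC was the lowest over a gene's start sites, which ties it to their number, but among genes with 1 start site these shares were 41.3% ± 2.86 and 13.3% ± 1.76 (both SD, n = 3).

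**Figure D2:**
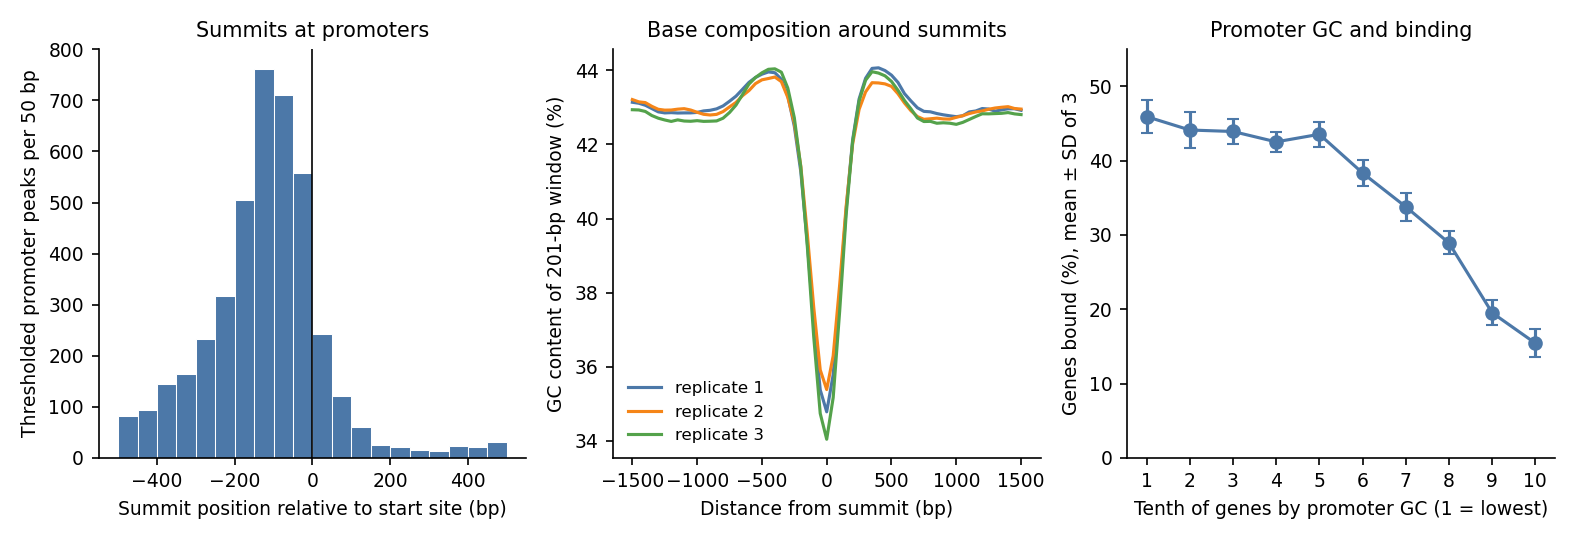
Left, number of thresholded promoter summits per 50 bp by position relative to the start site (bp); middle, mean GC content (%) within 100 bp of positions by distance from the summit (bp) in 3 replicates; right, genes bound (%, mean ± SD of 3 replicates) in 10 classes of promoter GC. Summits peak between -150 and -100 bp, GC falls to 34.0 to 35.4% at the summit, and the bound share falls from 45.9% to 15.4%.

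The strongest promoter peak lay 89 bp upstream of CG14100 (dm6, 3L 19590373 to 19590875) and had rank 1 in the pooled list and in each replicate. The next promoter peaks were 136 bp upstream of mRpL41, a protein of the mitochondrial ribosome (2R 15217547 to 15218037, rank 3 in the pool and in each replicate), and 128 bp upstream of Art3 (3R 15229275 to 15229777, pooled rank 4, replicate ranks 5.33 ± 2.89, SD, n = 3). The Art3 window also held the start site of mRpS10, another mitochondrial ribosomal protein. Ugalt, a nucleotide sugar transporter, followed at pooled rank 7 (X 2703642 to 2704145). The other promoter peaks down to pooled rank 28 lay at CG18428 and eIF4EHP, CG18549, px, ph-p, Pal1 and Pdrg1, Fkbp14, CG1888, CG5611 and Mtl, Chro and Ssl1, CG9147 and Fbw5, Tcs5 and CHMP2B, PNPase, CG13390 and CG17294, CG31145, Lon and PIG-F, and cu. Among these, PNPase and Lon act in mitochondria, ph-p is a Polycomb group protein and Chro a chromatin protein. Peaks were named only if found in all 3 replicates; their lowest rank in any replicate was 41, and 9 of the 20 windows held start sites of more than 1 gene, so the peak was not assigned to 1 of them.

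Away from promoters, 2605 thresholded summits (29.9%) lay over 2 kb from any annotated start site, 1698 (65.2%) of them in introns and 867 (33.3%) in intergenic sequence. The strongest distal peak lay 12470 bp upstream of chinmo, which encodes a zinc finger regulator of neuronal temporal identity (2L 1638498 to 1639047, pooled rank 22, replicate ranks 24.7 ± 26.3, SD, n = 3). The next lay in intergenic sequence, 11910 bp from the nearest start site, that of CG13323 (2R 13035076 to 13035572, pooled rank 35). Then came peaks in an intron of Tlk, a protein kinase gene (X 3741974 to 3742441, rank 42), and in one of simj, which encodes a subunit of a chromatin remodelling complex (3L 10682689 to 10683258, rank 49). The last of the 6 lay in an intron of CG12769 (2R 8060785 to 8061226, rank 52) and 3336 bp from the nearest start site of the mitotic cyclin gene CycB (2R 22802733 to 22803196, rank 56). All 6 were found in the 3 replicates. Chromosome 4 held 34 thresholded peaks, 25.2 per Mb (replicates 28.2 ± 7.15, SD, n = 3), and the other chromosomes 59.6 to 70.4 per Mb.

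Of 9 genes of the CoRest complex and proteins linked to it, 6 carried a promoter peak, and ttk, CtBP and Lint-1 did not. CoRest had 2 summits, at pooled rank 533 in an intron (X 19521954 to 19523045, replicate ranks 500 ± 170, SD, n = 3) and at rank 2642 in its 5′ untranslated region, and reads of the transgene and of the endogenous gene were not told apart here. HDAC1 had 2 intronic summits, the stronger 446 bp from a start site (3L 4626934 to 4627519, rank 416, replicate ranks 392 ± 148, SD, n = 3). Su(var)3-3 had 1 summit, 73 bp from its start site (3L 20226086 to 20226529, rank 5352), found in 2 of 3 replicates. The zinc finger repressor gene chn had 5 summits, the strongest within 500 bp of a start site (2R 15128343 to 15128885, rank 137, replicate ranks 171 ± 74.0, SD, n = 3). The zinc finger repressor gene ttk had 4 intronic summits, the strongest at rank 2272 and 3583 bp from its nearest start site. The chromatin gene l(3)mbt had 2 summits just upstream of its start site, at ranks 4345 and 7321. As a list, the CoREST complex and its partners had a promoter peak at 6 of 9 genes (66.7%; replicates 70.4% ± 6.42, SD, n = 3), which did not pass Fisher's exact test (Benjamini-Hochberg adjusted p = 0.159 over 21 lists).

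Of 13945 protein-coding genes, 4930 (35.4%; replicates 35.5% ± 1.63, SD, n = 3) had a promoter peak. Of the 21 gene lists, 3 were bound more often than other genes. Ribosomal protein genes had a promoter peak at 79 of 92 members (85.9%; replicates 84.4% ± 0.628, SD, n = 3; Fisher's exact test, adjusted p = 2.68e-22). The highest ranks among them were RpL34b at 357, RpS27 at 457, RpL23A at 706 and RpL7 at 714, while RpL10Aa and RpL22-like, the first in the alphabet of the 13 without one, had none. Chromatin regulators had one at 20 of 23 members (87.0%; replicates 88.4% ± 2.51, SD, n = 3; adjusted exact p = 1.98e-06 by the same exact test), led by the Polycomb gene ph-p at rank 13, the insulator gene Cp190 at 46, the remodelling ATPase gene brm at 70 and the Polycomb methyltransferase gene E(z) at 104. Among the 3 without one were Su(var)2-10 and Su(var)3-9. Cell cycle and replication genes had one at 24 of 31 members (77.4%; replicates 78.5% ± 1.86, SD, n = 3; adjusted exact p = 1.18e-05), led by the ribonucleotide reductase gene RnrS at rank 328, the replicative helicase gene Mcm2 at 607, and Rbf2 and Dp, partners of E2F factors, at 638 and 683. The cyclin genes CycD and CycE had none.

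A further 3 lists passed below other genes, but 1 of them, the histone genes, could hardly hold a peak. Odorant and gustatory receptor genes, which serve smell and taste, had a promoter peak at 1 of 119 members (0.840%; exact 95% interval 0.0213 to 4.59%, adjusted exact p = 1.80e-20 by Fisher's exact test). That member was Gr63a, a subunit of the carbon dioxide receptor, at rank 7043, and Gr10a and Gr10b had none. Cuticle protein genes had one at 3 of 70 (4.29%; replicates 2.86% ± 1.43, SD, n = 3; adjusted exact p = 3.47e-09), namely Cpr65Ea at rank 5795, Cpr65Av at 8151 and Cpr67Fa1 at 8565, and Cpr100A and Cpr11A had none. Without a replicate, which leaves fewer peaks, the cuticle protein share was 1.43 to 2.86%, still below other genes. Replication-dependent histone genes had none at 0 of 111, which allows a share of up to 3.27% (exact 95% interval), among them His1:CG31617 and His1:CG33801. These are near-identical copies: on average only 0.860% of the 31-base sequences around their start sites occur once in the assembly, so a missing peak there does not show missing binding.

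The other 14 lists did not pass the threshold by Fisher's exact test, and replicate values are means ± SD (n = 3). The list of Hox cluster genes, with cad from outside the clusters, had a promoter peak at 7 of 11 members (63.6%, replicates 51.5% ± 5.25, adjusted exact p = 0.159), with Dfd at rank 2102 and cad at 3654. Wnt and Hedgehog genes had one at 11 of 21 (52.4%, replicates 54% ± 7.27, adjusted exact p = 0.216), with rdx at 590 and nkd at 689. The list of gap and pair-rule genes, which also holds segment polarity genes such as wg, had one at 10 of 21 (47.6%, replicates 44.4% ± 14.5, adjusted exact p = 0.451), with oc at 1389 and wg at 1534. Its share was 28.6% without replicate 1 or replicate 2, which leaves fewer peaks. The list of neural progenitor and proneural genes, which also holds elav, a gene of differentiated neurons, had one at 11 of 24 (45.8%, replicates 40.3% ± 8.67, adjusted exact p = 0.470), with elav at 78 and brat at 2161. For the BMP pathway and dorsal genes it was 10 of 23 (43.5%, replicates 42.0% ± 15.3, adjusted exact p = 0.718), with tup at 2127 and pnr at 2232. For germline genes it was 8 of 19 (42.1%, replicates 43.9% ± 6.08, adjusted exact p = 0.830), with piwi at 413 and bgcn at 1167. Proteasome genes had one at 20 of 48 (41.7%, replicates 43.1% ± 6.70, adjusted exact p = 0.550), with Rpn5 at 1257 and Rpn11 at 1392. Regulators of gut, trachea, blood and ectoderm had one at 7 of 18 (38.9%, replicates 44.4% ± 5.56, adjusted exact p = 0.997), with trh at 807 and grn at 899.

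Heat shock genes had a promoter peak at 5 of 14 members (35.7%, replicates 33.3% ± 4.12, adjusted exact p = 1), with Hsp27 at 268 and Hsp26 at 1625. Of these 14, 6 are Hsp70 copies with 0 to 28% unique sequence around their start sites, where a missing peak shows as little as at the histone genes, and of the other 8 members 5 had a peak. Ecdysone genes had one at 7 of 20 (35%, replicates 38.3% ± 2.89, adjusted exact p = 1), with E23 at 40 and Eip75B at 338. Muscle and mesoderm genes had one at 9 of 26 (34.6%, replicates 33.3% ± 2.22, adjusted exact p = 1), with sls at 319 and tin at 564. Notch pathway genes had one at 7 of 21 (33.3%, replicates 38.1% ± 4.76, adjusted exact p = 1), with E(spl)m3-HLH at 99 and numb, an inhibitor of Notch, at 179. Terminal neuronal genes had one at 5 of 28 (17.9%; replicates 13.1% ± 4.12, SD, n = 3; adjusted exact p = 0.159), with Nrx-1 at 1150 and eag at 6370. Against random lists with the same number of start sites and gene length, which averaged 48.5%, the terminal neuronal share was lower (adjusted p = 0.00360 by permutation). The terminal neuronal share was 7.14% without any 1 of the replicates, which leaves fewer peaks. Testis genes had one at 2 of 18 (11.1%, replicates 7.41% ± 3.21, adjusted exact p = 0.135), twe at 3597 and mia at 7526, the latter found in 1 replicate only.

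**Figure D3:**
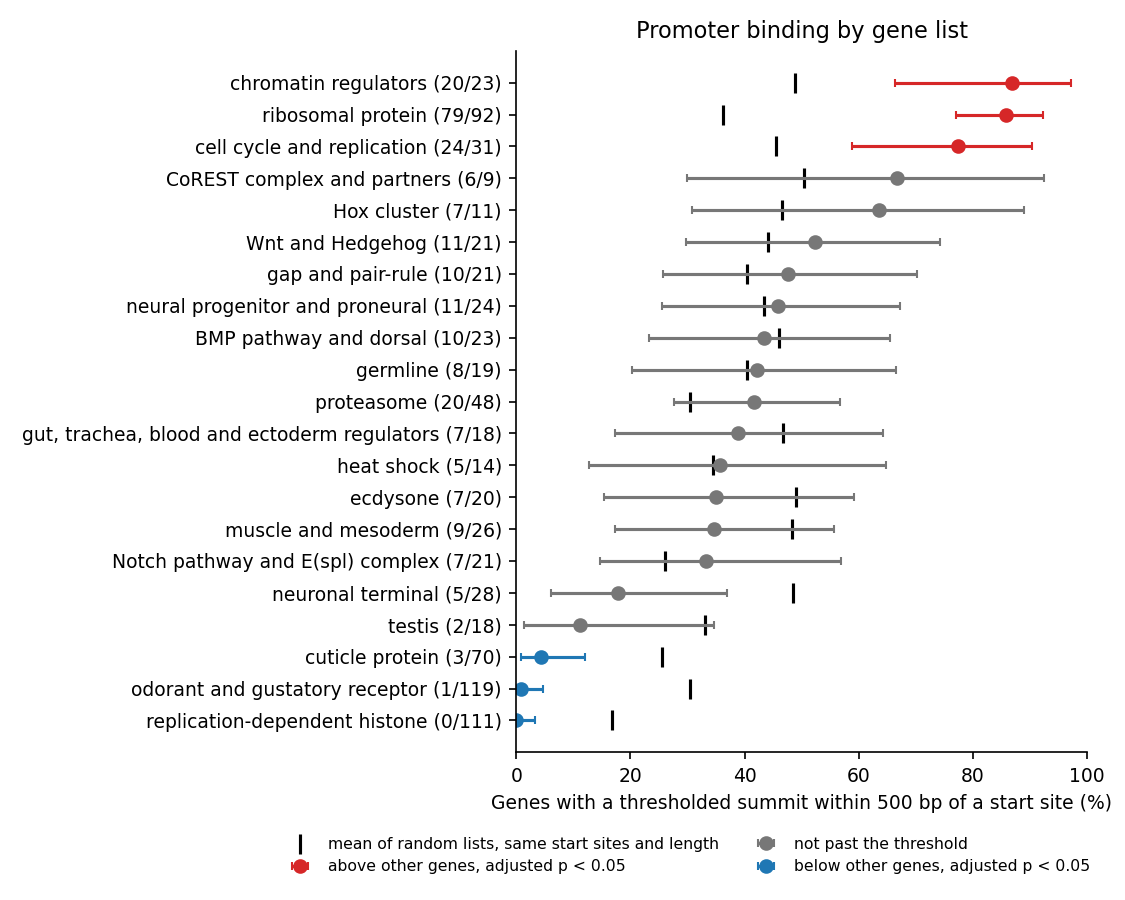
Share of each list's genes with a thresholded summit within 500 bp of a start site (%), with exact 95% intervals; black ticks give the mean of random lists matched on start sites and gene length. Ribosomal protein (85.9%), chromatin (87.0%) and cell cycle genes (77.4%) lie above other genes, and receptor (0.840%) and cuticle protein genes (4.29%) below; histone genes (0%) lack unique sequence for a peak.

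Divergent promoters were bound far more often than single ones. Of 1903 plus-strand genes with a minus-strand start site head to head within 500 bp, 1219 (64.1%) had a promoter peak, against 2504 of 10130 genes without such a neighbour (24.7%). The ratio was 2.59 (95% interval 2.47 to 2.72; replicates 2.58 ± 0.0504, SD, n = 3; Fisher's exact test, p = 5.85e-235). A divergent window holds the start sites of at least 2 genes, and the peak was not assigned to either. Part of this ratio can therefore be built in, and binding per start site was not compared. Genes of the X chromosome had a promoter peak in 835 of 2196 cases (38%), against 4074 of 11669 on the 4 large autosome arms (34.9%). The ratio was 1.09 (95% interval 1.03 to 1.16; replicates 1.08 ± 0.0532, SD, n = 3; exact p = 0.00555), but it was 0.908 (exact p = 0.0347) among the 4360 strongest thresholded peaks, and the call was kept in 4 of 8 alternatives, so a higher share on the X was not established.

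Promoter peaks were rich in the sequences that the core promoter factors DREF, M1BP and BEAF-32 bind. Within 100 bp of the summit, the DREF site (DRE) was present at 9.19% of promoter peaks against 2.99% of promoters without a peak (3.06-fold; replicates 3.15 ± 0.208, SD, n = 3; adjusted exact p = 4.12e-32 by Fisher's exact test). The M1BP site was present at 5.19% against 1.59% (3.24-fold; replicates 3.90 ± 0.840; adjusted exact p = 2.42e-19) and the BEAF-32 site at 41.5% against 28.1% (1.48-fold; replicates 1.43 ± 0.0363; adjusted exact p = 2.39e-36), with SD over 3 replicates. These windows held 35.1% GC and the control promoters 40.7%. With control promoters of the same GC content, chosen after seeing the data, the ratios were 2.97 for DREF, 3.50 for M1BP and 1.45 for BEAF-32, all still past the threshold. The BEAF-32 consensus CGATA lies within the DRE consensus TATCGATA, so each DRE match also counts for BEAF-32. BEAF-32 matches outside a DRE were not compared. Of the other 3 sequences more frequent than in the unmatched controls, the homeobox core (1.55-fold) and Ohler motif 6 (1.93-fold) fell to 1.04 and 1.31 with matched controls and no longer passed (adjusted exact p = 0.577 and 0.284), and poly-A turned from 1.15 to 0.818.

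The consensus of the initiator, a core element of many developmentally regulated promoters, was less frequent near promoter summits than in controls (15.8% against 24.0%, adjusted exact p = 1.72e-19 by Fisher's exact test, and 0.702-fold with matched controls). The GATA site was also less frequent (5.50% against 8.69%, adjusted exact p = 8.60e-08, and 0.630-fold with matched controls). Both held in 20 of 20 other draws of unmatched controls. The median promoter summit lay at -114 bp, so many windows of 100 bp on each side did not reach the nearest start site. The initiator value therefore describes sequence around the summits and does not show that bound promoters lack an initiator at the start site. With windows 1 kb from the summits as controls, the initiator was at 0.941-fold (adjusted exact p = 0.313) and GATA at 0.931-fold (adjusted exact p = 0.483). Those windows were not matched on GC, with 44.9% against 35.1% at the promoter peaks. The GAGA factor, Zelda, Snail-type, CACGTG, poly-CA and AGGACAAT (Tramtrack) sequences were also less frequent than in unmatched controls, but none of them differed from matched controls. In 20 other draws of unmatched controls this held 20 times for the Snail-type, 19 for the GAGA, 17 for the Zelda and 13 for the poly-CA sequence, but 3 times for CACGTG and 2 times for AGGACAAT. With matched controls, 3 further sequences were more frequent: the sequence CAGCACC from the site of Charlatan and its vertebrate counterpart REST (1.91% against 1.04%, 1.83-fold, adjusted exact p = 0.00410), the E-box CAGCTG (1.26-fold) and Ohler motif 7 (1.2-fold). Of these, Ohler motif 7 also passed in 5 of the 20 unmatched draws, and the other sequences in none. Some forms of Ohler motif 7 contain the E-box CAGCTG, so the same windows can count for both. The median ratio of CAGCACC in the unmatched draws was 0.958 (0.733 to 1.11). Matched controls came from only 1 draw, so how far these results depend on the draw is unknown. The TATA box (0.793-fold, adjusted exact p = 0.000109) and the SoxN/D sequence (0.581-fold, adjusted exact p = 0.0489) were less frequent with matched controls, and in 0 and 1 of the 20 unmatched draws. The short consensus used for the downstream promoter element was present in 99.5% of windows and controls, so it could not differ.

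**Figure D4:**
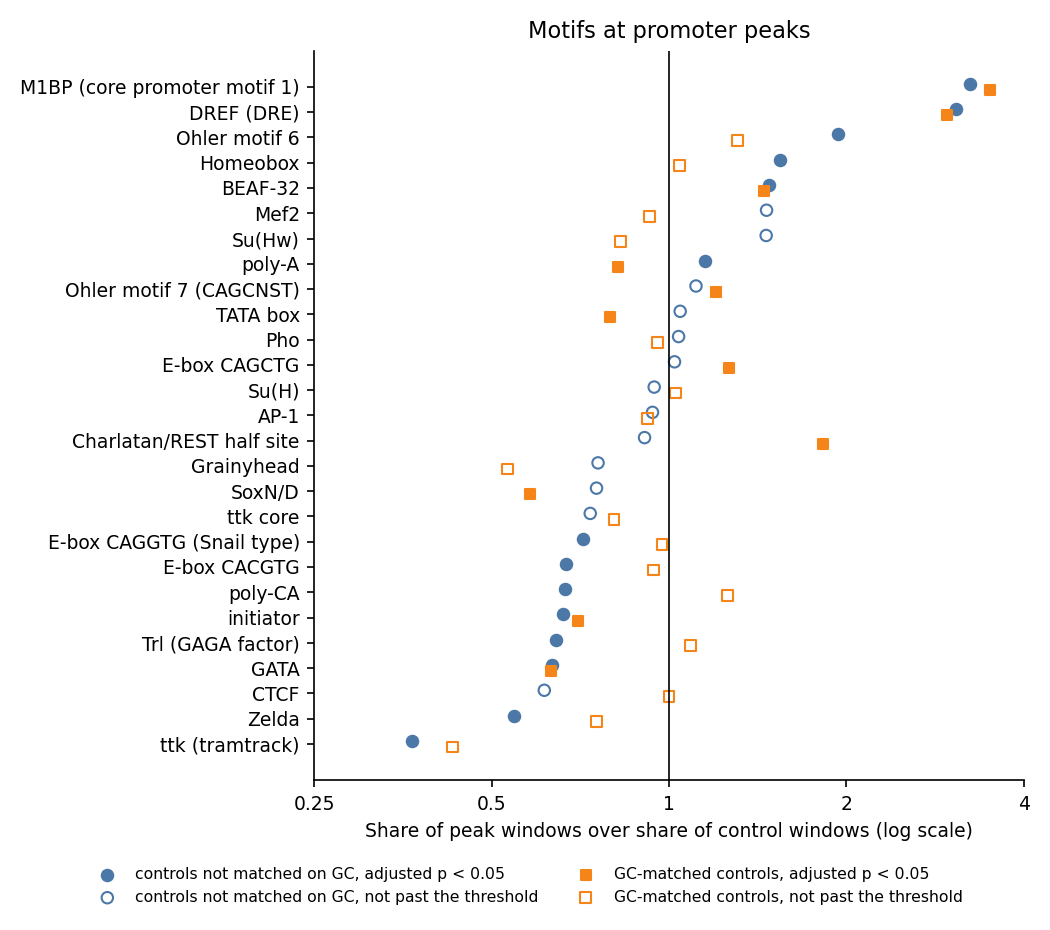
Ratio of the share of promoter peak windows with a motif to that of control windows (log scale), for controls not matched on GC (circles) and matched on GC (squares); filled symbols passed the threshold. M1BP (3.24 and 3.50), DREF (3.06 and 2.97) and BEAF-32 (1.48 and 1.45) are more frequent at peaks with both kinds of control.

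At the 2605 distal peaks, 3 of the 28 sequences were more frequent than in distal windows of the same GC content. The insulator protein sequences of CTCF were present at 25 peaks and 7 controls (3.40-fold, adjusted exact p = 0.0316 by Fisher's exact test) and those of Su(Hw) at 23 and 6 (3.62-fold, adjusted exact p = 0.0316). The GATA site was present at 7.26% of peaks against 5.30% (1.37-fold, adjusted exact p = 0.0395). With 20 other draws of control windows, Su(Hw) passed in 9, CTCF in 8, GATA in 4 and the AP-1 site, which did not pass here, in 6, and with any 1 replicate left out, which leaves fewer peaks, none passed. The ratios without a replicate were 3.67 to 3.89 for CTCF, 2.64 to 2.82 for Su(Hw) and 1.27 to 1.32 for GATA. In windows of 250 bp CTCF and GATA still passed, but Su(Hw) did not (1.42-fold, adjusted exact p = 0.455). With windows 1 kb from the summits as controls, CTCF turned to 0.526-fold, Su(Hw) was at 6.71-fold and GATA no longer passed at 1.23-fold. Those windows were not matched on GC, with 40.5% against 33.6% at the distal peaks.

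The 3 replicates shared many of their strongest peaks. Of 10736 clusters of summits from the 8721 strongest peaks of each replicate, 5892 (54.9%) held all 3 replicates, against 0.0352% and at most 0.0636% with random placement, and 46.8% of clusters did when intervals had to overlap by 50% of each. The thresholded list was selected from these same replicates, so finding its peaks in them is support for single peaks and no separate measure of similarity. Of the thresholded peaks, 87.5% were found among the strongest 8721 peaks of replicate 1, 80% in replicate 2 and 85.6% in replicate 3 (mean 84.4% ± 3.93, SD), and 5700 (65.4%) in all 3. In the full replicate lists, 95.4% ± 1.71 (SD, n = 3) were found, and 6 peaks in none. Across the thresholded peaks found in both replicates of a pair, which are not independent, Spearman's rho of the signal was 0.793, 0.806 and 0.861 (mean 0.820). The thresholded peaks were exactly the 8721 pooled peaks of highest signal, and 3949 genes were bound in the thresholded list and in each replicate.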

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

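The comparison with tRNA genes was chosen only after its result was seen, and the tests matched on GC content and on unique promoter sequence were added after the peak lists were seen. Of the 21279 pooled peaks below the authors' threshold, which the comparisons did not otherwise use, 22.0% (4675) were found in the full lists of all 3 replicates. This value is given only because these peaks were not otherwise used. The pooled list came from the same replicates, so recurrence is partly built in, no reference value fits it, and it does not show binding. A share of 25.8% of these recurring peaks lay at promoters, against 20.1% of all peaks below the threshold.

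The summits were AT-rich and almost never in coding sequence. If base composition alone set where peaks were called, random positions of the same GC content would give the same shares, but these had 3.99 to 4.90% in coding sequence outside promoters, against 0.149% observed, and 10.3 to 12.0% at promoters, against 47.5%. A position in broad AT-rich regions was argued against by the GC content at 1 kb from the summits, which was above that at the summits by 7.42 percentage points or more in each replicate. What stays open is a part of the gradient due to GC bias of the libraries, since binding fell with promoter GC, and open chromatin, which may favour AT-rich promoter sequence in any precipitation. No biological explanation was tested, as the design has 1 group.

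Ribosomal protein genes and divergent promoters were bound above other genes. False enrichment at all highly transcribed genes would have to include tRNA genes, but 25 of 290 of these (8.62%) had a summit within 500 bp, against 35.4% of protein-coding genes (Fisher's exact test, p = 1.55e-25). This comparison was chosen after its result was seen. The protein-coding genes were not limited to highly transcribed ones, and some have several start sites, so it does not settle the question. Promoter GC did not account for the ribosomal protein genes or the divergent promoters. The ribosomal protein share lay at percentile 100 of 10000 random lists matched on promoter GC, start sites and gene length. Within classes of promoter GC, the divergent ratio was 2.45. The divergent ratio was not adjusted for the further start sites that a divergent window holds, so this explanation stays open for part of it. Of 21 ribosomal protein genes without an M1BP, DRE or CGATA match, 16 (76.2%) were bound, against 23.5% of other genes without one (Fisher's exact test, p = 5.62e-07). These motifs did not account for the binding of those 21 genes. The other 71 ribosomal protein genes carried a match and were not tested, so for them these motifs stay open. Other core promoter sequences were not part of this test. False enrichment that is restricted to open promoters of genes read by RNA polymerase II could give the same peaks. It stays open without a mock precipitation. Apart from the M1BP, DRE and CGATA motifs, no biological explanation was tested.

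Histone, receptor and cuticle protein genes had no or few peaks. For the histone genes, reads that cannot be placed on 1 copy are a candidate explanation: 0.860% of the 31-base sequences around their start sites occur once, their cluster (2L 21416953 to 21541681) held 0 summits in every list, and of 257 promoters with under 20% unique sequence, 111 of them the histone genes themselves, 0 had a peak. Whether histone genes are bound stays open. For the receptor and cuticle protein genes this was argued against, since 98.2% of their sequences occur once, and so was promoter GC, which would give 22.8% bound, against 2.12% (4 of 189) observed. Genes that are closed or silent in most embryonic cells may explain these, but no accessibility or expression data were analysed here, and no biological explanation was tested.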

How the results depend on the processing

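The tests matched on GC content, those on unique promoters and the other control draws were chosen only after the data were seen. Under every alternative tried, the promoter share (37.3 to 55.8%) and the divergent ratio (2.04 to 3.23) kept their direction and side of the threshold. So did the calls for ribosomal protein, chromatin, cell cycle, receptor and cuticle protein genes. DRE, M1BP and BEAF-32 at promoter peaks did as well, but their ratios depended on the control. They were 2.53 to 21.8 for DRE, 2.42 to 14.9 for M1BP and 1.22 to 1.89 for BEAF-32, each highest with flanking windows. The histone genes, at 0% throughout, could not have changed, as their sequence is not unique. Cuticle protein genes moved from 4.29% to 1.43 to 2.86% without a replicate, and gap and pair-rule genes from 47.6% to 28.6 to 38.1%; the cause was not tested. Lists above other genes numbered 6 in the 17442 strongest pooled peaks, which added the CoREST complex, BMP and Wnt lists. The gap and pair-rule list passed above other genes in 1 alternative only (matched on promoter GC, adjusted permutation p = 0.0383), and terminal neuronal genes passed below in 5 of 10.

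Sharing by all replicates moved to 56.5% for intervals overlapping by 1 bp, 46.8% for intervals overlapping by 50% of each, and 64.8 to 68.0% without a replicate, where sharing needs only 2 lists. The share found in a replicate moved to 76.2% at 50 bp and 88.4% at 250 bp, by construction, and rho was 0.793 to 0.861 without a replicate. Distal motifs numbered 0 in windows of 50 bp, 6 in windows of 250 bp, 0 in the 4360 strongest peaks, 7 in the 17442 strongest pooled peaks, 1 as the median of other draws, and 0 to 0 without a replicate, by Fisher's exact test; at an unadjusted p below 0.05 the counts of 0 became 3 in windows of 50 bp and 2 to 4 without a replicate, and stayed 0 in the 4360 strongest peaks. Fewer peaks lower the power of these tests, and the cause was not tested further. The X ratio was 1.05 with promoters of 250 bp (exact p = 0.219), 0.908 in the 4360 strongest peaks and 1.04 to 1.09 without a replicate (1.04 without replicate 1 or replicate 3, exact p = 0.302 and 0.320). It was 1.09 with promoters of 1000 bp (exact p = 0.00396), 1.14 in the 17442 strongest pooled peaks (exact p = 6.00e-08) and 1.12 within classes of promoter GC (bootstrap, p = 0.001, the smallest possible), so 4 of 8 alternatives kept the call; the cause was not tested. GAGA sequences turned to 1.2 in windows of 250 bp and poly-A to 0.818 with GC-matched promoters. CTCF at distal peaks turned to 0.526 with flanking windows, which were richer in GC than the peaks. The causes were not tested. Unknown depth limits what a missing peak can show.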

Other observations

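The tests in this part were set after the peak lists were seen and before their own results, except the rule on which short sequences the fixed motifs cover, which was refined after the result was seen, and the shares of genes with any distal summit and means without 2 genes, which were chosen only after the result was seen. Distal summits per gene were higher in Wnt and Hedgehog, BMP and ecdysone genes than in other genes of their length, carried in large part by 2 genes in each list, and not in Notch pathway genes (0.143 per gene against 0.202, adjusted permutation p = 1). Wnt and Hedgehog genes held 2.29 distal summits per gene, against 0.822 in random lists of the same gene length (adjusted permutation p = 0.0168 over 21 lists), BMP pathway and dorsal genes 1.70 against 0.542 (adjusted p = 0.0196) and ecdysone genes 2.70 against 1.23 (adjusted p = 0.0483). Of the summits, fz2 and fz held 21 of 48, ush and shn 22 of 39, and ftz-f1 and Eip75B 23 of 54, and without these genes the means were 1.42, 0.810 and 1.72. By the share of genes with at least 1 distal summit, none of the 3 lists passed (adjusted permutation p = 0.343, 0.157 and 0.0546). Terminal neuronal genes held fewer, 0.0714 against 1.06 (adjusted permutation p = 0.00420), and the other 17 lists did not pass. The genes with the most distal summits in their span were kirre with 20, sbb with 13, hth, ftz-f1 and ush with 12 each, and fz2 and Eip75B with 11 each, named after their values were seen. Of these, fz2 is a Wnt receptor, ush a regulator of dorsal and blood development, and Eip75B and ftz-f1 are nuclear receptors of the ecdysone response.

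Peaks were densest in a 50-kb window at tara (3R 16200001 to 16250000), with 20 thresholded summits and 20.7 ± 0.577 in the replicates (SD, n = 3). Other dense windows held aop, a repressor of receptor tyrosine kinase signalling (2L 2150001 to 2200000, 17 summits), and brk, a repressor of BMP targets (X 7300001 to 7350000, 16 summits). Of non-coding genes, 370 of 3261 ncRNA (11.3%), 16 of 269 snoRNA (5.95%), 6 of 32 snRNA (18.8%), 16 of 268 pseudogenes (5.97%) and 0 of 99 rRNA genes had a summit within 500 bp of a start site. The rRNA genes have a median of 0% unique sequence there, and no chance share was computed, so these are values only.

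A hypothesis was that developmental regulators hold more distal peaks than other genes of their length. The 6 lists of Hox, gap and pair-rule, neural, BMP, Wnt and gut to ectoderm regulators (117 genes) held 1.06 distal summits per gene against 0.481, at percentile 100 of 10000 random lists (permutation p = 0.0002, the smallest possible). Without ush and fz2 the mean was 0.878, and 36 of the 117 genes (30.8%) had any distal summit, against 19.5% in random lists (permutation p = 0.000400), so this held. Gap and pair-rule genes (0.0476 against 0.0584) and neural progenitor genes (0.250 against 0.405) did not share in this by value, and matching on gene length leaves open whether open chromatin would give the same.

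A second hypothesis was that the strongest promoter peaks carry DRE and M1BP sites more often than weak ones, and the opposite was found. Of the 1381 strongest promoter peaks 4.92% had a DRE, against 13% of the 1381 weakest (Fisher's exact test, adjusted p = 1.21e-13), and 1.67% had an M1BP site, against 6.23% (adjusted p = 4.56e-10). The strongest had a GC content of 31.9% and the weakest of 37.4%, so base composition may account for part of this, which was not tested.

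Another hypothesis was that peaks carry short sequences outside the 28 fixed motifs. The 8-base sequence most enriched at distal peaks of 2L, 2R and 3L, CACTGAGA, was also more frequent on 3R, X and 4. It was present at 62 of 1157 peaks (5.36%) against 10 GC-matched controls (0.864%, Fisher's exact test, adjusted p = 7.41e-10 over 10 sequences). No fixed motif covers it in full, but its reverse strand holds TCAGT, all but the last base of the initiator consensus. The initiator consensus itself was not more frequent at distal peaks (1.03-fold, adjusted p = 0.843 by Fisher's exact test). CACTGAGA occurred at 159 of 2605 distal peaks (6.10%), none of them in an annotated transposable element, and at 1.11% of promoter peaks. Overlapping sequences such as CTCAGTGC, TCAGTGCA and ACACTGAG passed as well, which may mark a longer site whose binding protein was not sought here. At promoters the leading sequence was GGTCACAC (6.73% against 2.13%), which is part of the M1BP consensus, so it brought nothing beyond the fixed motifs. Of the 10 promoter sequences tested, CAGCACTG, CAGCCCTG and CATCTCTA matched no fixed motif in full over their overlap (2.52%, 3.25% and 2.80% of peaks against 0.729%, 0.897% and 0.224% of controls), although CAGCACTG shares all but the last base of the Charlatan sequence CAGCACC.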
